A study of Homo sapiens with 4 samples.

How the data were processed

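Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in NCI-H1944, an established human lung adenocarcinoma cell line. Per the labels, cells received either DMSO, the solvent control, or 100 nM of BAY-1217389, an inhibitor of the mitotic kinase MPS1 (gene symbol TTK), for 48 h. The drug was then washed out and the cells grew for another 24 h, and about 50000 cells per library went into a transposition of 30 min. The 4 libraries form 2 groups of 2, named DMSO and MPS1i below. The labels number the replicates but do not say whether they came from separate cultures. A p-value thus measures at most the spread between these libraries, which may be technical. Some tests below do not measure even that. Camera with a preset correlation, Fisher's exact test and permutations over chromosomes rest on the number of peaks, promoters or chromosomes.

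The authors deposited raw counts per peak, as whole numbers without normalization, for 93576 peaks in the 4 libraries, with the position, length and annotation of each peak. Per the submitters' processing notes, the tools were Bowtie2, MACS2, featureCounts and HOMER, and the genome build was named GRCh38 and hg38. Their versions, settings and filters, the treatment of duplicate and mitochondrial reads, any shift of reads for the transposase, and whether peaks were called per library or on pooled reads are not given in the sources used here. Between 57.3% and 62.9% of the counts in a library were even numbers, which is more than single reads would give. Both mates of a pair may therefore have been counted, and counting error is then larger than the counts themselves show. Coordinates are given as the deposited table gives them; whether its starts count from 0 or 1 is not given in the sources used here.

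Total counts in peaks were 22950237 and 21420575 for DMSO replicates 1 and 2, and 26134372 and 22599145 for MPS1i replicates 1 and 2. The median count per peak ranged from 102 to 138 across libraries. Between the libraries of a group, the chi-square per degree of freedom over peaks was 1.86 for DMSO and 1.87 for MPS1i on the counts as deposited, and 0.929 and 0.937 on counts divided by 2. If both mates were counted, the libraries of a group thus differed at single peaks by no more than sampling noise, and p-values for peaks reflect little beyond counting error. Over chromosome sums it was 2.98 for DMSO and 7.80 for MPS1i even on counts divided by 2, more than sampling noise gives, so the 4 were kept as separate libraries. No further per-sample column was present.

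Gene names came from the deposited annotation, which assigns each peak to the nearest transcription start site (TSS). They were updated through the gene identifiers with a RefSeq gene table of GRCh38.p14, which matched 93168 of 93318 identifiers and restored 12 names that a spreadsheet had turned into dates. Another 258 peaks had no gene name. The nearest gene need not be the gene that a peak regulates, nor the one it lies in. Introns and UTRs are those of the transcript that the deposited annotation names.

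Counts were tested with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter, which left 93566 peaks, and Benjamini-Hochberg adjustment at 0.05. Standard errors (SE) of log2 fold changes were taken from the quasi-likelihood F statistic, and normalised counts are CPM, the usual scaling of counts to the library size, here TMM-scaled. For promoters, the counts of the 11865 peaks annotated as promoter-TSS were summed per gene, which gave 10944 genes, and tested with the TMM factors of the peak table. The shares of changed promoter and distal peaks were compared with a two-sided Fisher's exact test. The 16 gene lists were fixed before the data were examined: interferon-stimulated genes, RNA and DNA sensing, NF-kB and inflammatory cytokines, p53 targets, senescence-associated secretion and matrix, mitosis and spindle checkpoint, DNA replication and E2F targets, MHC class I antigen presentation, AP-1 and immediate early genes, Hippo and YAP/TEAD targets, epithelial-mesenchymal transition, lung and gut epithelial lineage, interferon response repressors and chromatin silencing, unfolded protein and proteotoxic stress, and markers of immune cells and of fibroblasts and endothelium. None of the other lists shares a gene with the interferon list. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over the 16 lists. A list's peaks were those whose nearest TSS, within 50000 bp, was that of a list gene. Fry and camera with an estimated correlation were run beside camera with the preset one. Camera takes its degrees of freedom from the number of tested items with a preset correlation. With an estimated one it takes them from the 4 libraries alone and has little power here. A call lost there need not reflect correlation between members of a list. Counts were also summed per chromosome, with the library size as the only scaling, and per 10 Mb window, for chromosomes 1 to 22 and X, and tested with edgeR.

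The rule for named peaks, fixed at the same time, took the 10 largest rises and the 10 largest falls among peaks past the threshold that had a mean of at least 50 counts, both MPS1i libraries on the same side of both DMSO libraries, and a nearest gene within 100000 bp that had a symbol other than a LOC, LINC, RNA, antisense or pseudogene name, with 1 peak per gene. It took 5 promoters each way, and up to 3 peaks or promoters with the smallest p for each list. TTK, CDKN1A, MDM2, ISG15, IFIT1, CXCL10, CCL5, RIGI, MAVS and CXCL8 were always given. Genes named outside this rule are said to be so where they appear.

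The alternatives were DESeq2 1.42.0, RLE size factors, library size alone, loess offsets that remove any trend of the change with abundance, no filter on low counts, a tested fold above 1.2 (glmTreat), the replicate number as a block, each library left out in turn, promoters as peaks within 1000 bp of a TSS, a limit of 10000 bp for list peaks, 5 Mb windows, and distal peaks only for chromosomes. The loess offsets were planned; counts divided by 2, loess-corrected chromosome sums and tests of repeat families and elements were added after the data were seen. For promoters, DESeq2 estimated its size factors from the promoter counts alone, not from the peak table. Motif tests and offsets for GC content had been planned and were not run, since they need the genome sequence, which was not used here. The test was checked on counts simulated for the 93566 peaks of the MPS1i against DMSO comparison with 200 changed peaks. It recovered 4% of those changed 1.2-fold, 34% at 1.5-fold, 72% at 2-fold and 100% at 4-fold, with 4 false calls, and camera called a simulated set of 150 peaks raised 1.2-fold and 0 of the unchanged sets.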

Results

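The study compared open chromatin in NCI-H1944 lung adenocarcinoma cells after a pulse of the MPS1 inhibitor BAY-1217389 with that of cells given DMSO. MPS1 is a kinase of the spindle assembly checkpoint, and cells that divide without it missegregate chromosomes. There were 2 libraries per group, and between 21420575 and 26134372 counts fell in peaks per library. Of the 93576 peaks, 40.7% were annotated as intergenic, 39.7% as intronic and 12.7% as promoter-TSS. The share of counts in promoter peaks lay between 31.7% and 32.2% in all 4 libraries. Log2 CPM correlated across peaks with a Pearson's r of 0.981 between the DMSO libraries, 0.984 between the MPS1i libraries and 0.953 to 0.957 between groups; peaks are not independent replicates.

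Of the 10 largest rises among peaks eligible for naming, 6 lay nearest to genes of the fixed list of interferon-stimulated genes. The largest with TMM was at RIGI, which encodes a sensor of viral RNA. Its peak (hg38 chromosome 9, 32529570 to 32529888, intergenic, at -3533 bp from the TSS, in an MER57E2 repeat) went from 0.282 ± 0.21 to 5.11 ± 0.028 CPM (SD, n = 2), an 18.1-fold rise. Peaks nearest to IFIT5, IFIT2 and IFIT3, of a family of interferon-induced antiviral proteins, rose 17.9-fold, 11.2-fold and 8.21-fold, and a peak nearest to MX1, an antiviral GTPase, rose 6.73-fold. Among the 10 largest falls, the most abundant peak was nearest to NR4A1, an immediate early nuclear receptor (chromosome 12, 52059962 to 52061246, intergenic), and went from 100 ± 7.8 to 37.9 ± 0.2 CPM (SD, n = 2).

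The peak nearest to IFIT5 (chromosome 10, 89404108 to 89405173) lay at -9928 bp from that gene's TSS, in the annotated 3' UTR of its relative IFIT1, and went from 0.742 ± 0.17 to 13.3 ± 0.63 CPM (SD, n = 2). On the log2 scale it rose by 4.16 (SE 0.22, edgeR adjusted p = 1.88e-42). The RIGI peak rose by 4.18 (SE 0.35, edgeR adjusted p = 4.79e-22). Its DMSO libraries held few counts, at 0.134 and 0.430 CPM, so the size of its rise is uncertain. With loess offsets the RIGI peak stood at 3.76, below the IFIT5 peak at 4.06. Other rises among the 10 largest were at an intronic MER57E1 repeat in HERC6 (3.78), in an intron of ACO1 (3.35), a neighbour of RIGI, upstream of NOS2, the inducible nitric oxide synthase (3.24), downstream of LY6E (3.10), and in an intron of IFI44L (2.97), with SEs of 0.15 to 0.31. The 10 largest falls were smaller, from -1.44 at a peak nearest to ATAD1, in an intron of PAPSS2, to -1.30 at an intron of OAS2. NR4A1 fell by 1.40 (SE 0.06, edgeR adjusted p = 2.14e-52). A peak upstream of AKR1B15, an aldo-keto reductase, fell by 1.38, and peaks nearest to ARHGEF10L, ECHDC1, PSMD1, LRFN4, HYAL1 and PURG fell by 1.31 to 1.42 (SE 0.23 to 0.27). OAS2, an antiviral oligoadenylate synthetase, moved both ways: its promoter peak (chromosome 12, 112978089 to 112979027) rose by 2.03 and an intronic one (chromosome 12, 113002202 to 113002560) fell by 1.30.

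**Figure D1:**
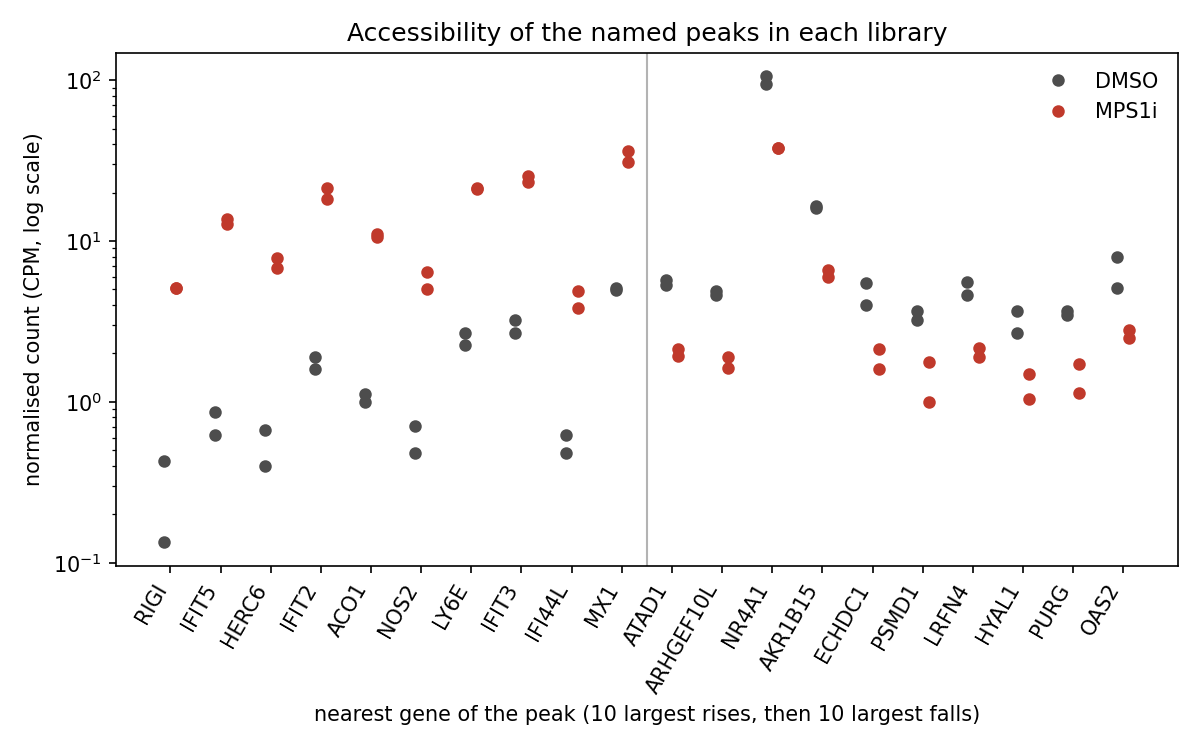
Normalised counts (CPM, log scale) in each of the 4 libraries for the 10 peaks with the largest rises and the 10 with the largest falls, named by nearest gene. Grey points are DMSO and red points MPS1i libraries. The naming rule required the 2 libraries of a group to lie on the same side of the other group, so this separation was set by selection. Group means went from 0.282 to 5.11 CPM at RIGI and from 100 to 37.9 CPM at NR4A1.

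Across all 93566 tested peaks, 11851 rose and 11909 fell (edgeR, adjusted p under 0.05), so 49.9% of the calls were rises. With library size as the only scaling the counts were 15224 and 8300, of which 64.7% were rises. At least 2-fold changes were more often rises, at 3581 against 298 falls, and with loess offsets at 1849 against 856. DESeq2 called 3816 rises and 5088 falls. Rises numbered 7409 without MPS1i replicate 1 and 7807 without MPS1i replicate 2. If both mates of a pair were counted, the spread between libraries of a group at single peaks was no larger than sampling noise.

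Weak peaks rose and strong peaks fell. In the tenth of peaks with the lowest abundance the median log2 fold change was 0.33, and 23% rose while 2.78% fell. In the tenth with the highest abundance it was -0.12, and 4.09% rose while 37.3% fell. Loess offsets, which remove this trend by construction, left 10674 rises and 9602 falls, of which 8388 rises and 7899 falls were shared with the TMM calls. Among the TMM calls, 65 changed sign.

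**Figure D2:**
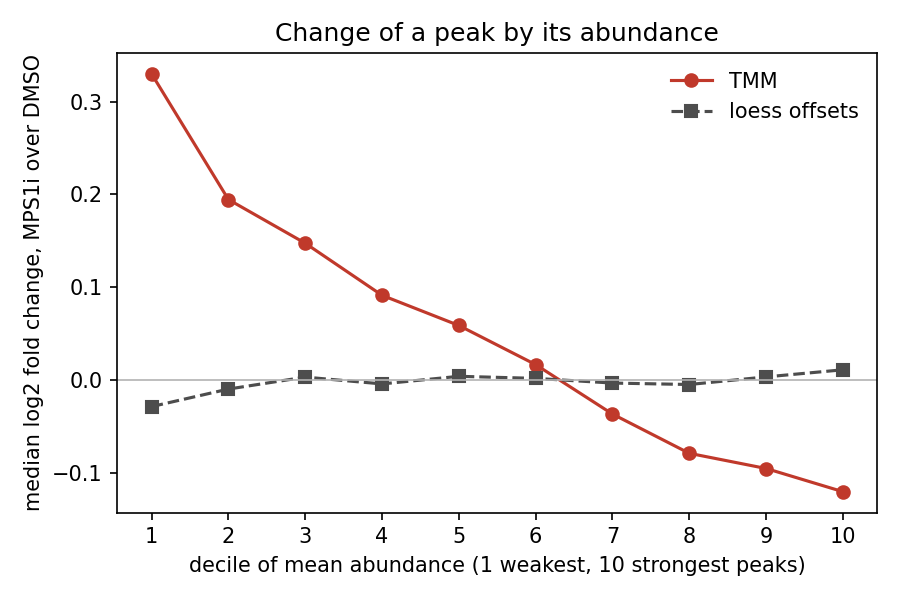
Median log2 fold change (MPS1i over DMSO) against the decile of mean abundance of a peak, with TMM (red circles) and with loess offsets (grey squares). With TMM the median goes from 0.33 in the weakest to -0.12 in the strongest decile.

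Genes of the interferon response opened as a group. Of the 120 peaks near 41 interferon-stimulated genes, 66 rose, 7 fell and 47 did not pass, and 72 rose and 9 fell when adjusted over the list alone. Of the 41 genes, 29 had rising peaks only, 3 falling peaks only, 4 both and 5 neither. Beside those above, ISG15, a ubiquitin-like modifier, rose by 2.41 (SE 0.14) at a peak 1835 bp from its TSS (chromosome 1, 1014881 to 1015784). The IFIT1 promoter differed by 0.22 (SE 0.12) and did not pass. CXCL10 was not the nearest gene of any tested peak within 50000 bp. The median log2 fold change of the list was 0.47, and 0.45 with loess offsets. The list rose relative to other peaks with limma camera (adjusted p = 1.97e-11). With an estimated correlation the call was lost (limma camera adjusted p = 0.30). The estimate was 0.0097, close to the preset 0.01, so correlation between the list's peaks does not account for the loss. Fry, which asks whether the list moves 1 way on balance, gave a limma adjusted p = 0.015. Of the other lists, fry passed for MHC class I (0.015) and for sensing (0.047) and gave 0.067 to 0.73 for the rest.

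Near genes of MHC class I antigen presentation, whose products display peptides to T cells, more peaks rose than fell. Of 49 peaks near 21 genes, 16 rose, 2 fell and 31 did not pass, and 20 rose and 2 fell when adjusted over the list alone. By gene, 10 had rising peaks only, 1 falling peaks only, 1 both and 9 neither. NLRC5, the transactivator of MHC class I genes, rose by 2.37 (SE 0.32) and 1.43 (SE 0.18) at a pair of intronic peaks, and the HLA-F promoter rose by 0.69 (SE 0.09). The median was 0.23 (limma camera adjusted p = 5.36e-04, lost at adjusted p = 0.32 with an estimated correlation). Here too the estimate, -0.0062, was not above the preset 0.01.

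Sensors of RNA and DNA and inflammatory cytokine genes held strong single rises, but their lists did not pass over all nearby peaks. For sensing, 23 of 93 peaks rose and 4 fell, with 24 and 4 adjusted over the list alone (limma camera adjusted p = 0.066, and 0.011 with loess offsets, 0.047 without DMSO replicate 1 and 0.041 without MPS1i replicate 1). The promoter of AIM2, a sensor of cytosolic DNA, rose by 1.75 (SE 0.21), and a peak nearest to DHX58, a relative of RIGI, rose by 0.84 (SE 0.10). The MAVS peak with the smallest p, at -3104 bp from the TSS, differed by 0.43 (SE 0.18) and did not pass, though it did with library size alone or without DMSO replicate 2. For NF-kB and cytokines, 36 of 137 peaks rose and 20 fell, with 37 and 20 adjusted over the list alone (limma camera adjusted p = 0.10, 0.038 with loess offsets and 0.0081 for peaks within 10000 bp). The promoter of CCL5, a T cell chemokine, rose by 1.53 (SE 0.20), CSF2 by 1.38 (SE 0.11) and TRAF1 by 1.35 (SE 0.14), while a peak near LIF fell by 0.65 (SE 0.06) and one near CXCL8 fell by 0.36 (SE 0.11). The CXCL8 call was lost with DESeq2, loess offsets, a fold above 1.2 or without DMSO replicate 2 or MPS1i replicate 2.

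Among peaks near genes of cell division, falls outnumbered rises, but the lists did not pass, and with loess offsets the falls dropped to 12 for mitosis and 8 for replication (limma camera adjusted p = 0.33 and 0.65). In the mitosis and spindle checkpoint list 5 of 84 peaks rose and 22 fell, with 6 and 23 adjusted over the list alone (limma camera adjusted p = 0.066). It passed for peaks within 10000 bp (limma camera adjusted p = 2.7e-04, lower) and without MPS1i replicate 2 (0.046). In the DNA replication and E2F list 4 of 85 rose and 16 fell, with 4 and 13 adjusted over the list alone (limma camera adjusted p = 0.10, 0.0097 within 10000 bp and 0.046 without MPS1i replicate 2). A peak near AURKB, a kinase of the chromosomal passenger complex, fell by 0.99 (SE 0.16), one near the proliferation marker MKI67 fell by 0.85 (SE 0.14), and one near MCM5, a subunit of the replicative helicase, fell by 0.59 (SE 0.10).

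The other lists held both rises and falls and did not pass. The peaks named for these 8 lists had SEs of 0.05 to 0.19 where none is given. Of 119 peaks near p53 targets, 14 rose and 22 fell (limma camera adjusted p = 0.41). Both promoter peaks of BBC3, which promotes apoptosis, rose, by 0.91 and 0.70, and a peak near KITLG fell by 0.65. The CDKN1A peak with the smallest p fell by 0.28 (SE 0.11) and that of MDM2 rose by 0.68 (SE 0.25). Each of these calls was lost under DESeq2, loess offsets or a fold above 1.2, that of CDKN1A also with library size alone and without any 1 library, and that of MDM2 without DMSO replicate 1 or either MPS1i library. In the AP-1 and immediate early list, 32 of 185 peaks rose and 49 fell (adjusted p = 0.13 with limma camera). ATF3, a stress-induced transcription factor, rose by 1.07, EGR1 fell by 0.97 and DUSP1 fell by 0.46. The list of senescence-associated secretion had 22 rises and 13 falls in 128 peaks, with TGFB1 at 0.82 and PLAUR at -0.31. The Hippo list had 19 rises and 21 falls in 125, with FJX1 at 1.61 and a pair of NUAK2 peaks at 1.28 (intergenic) and -0.69 (intronic). The epithelial-mesenchymal list had 21 of each in 124, where keratin peaks fell by 0.93 near KRT8 and by 0.62 near KRT18. The lung and gut lineage list had 14 rises and 20 falls in 118, with the airway mucin MUC5B at -0.81 and KRT5 at -0.68. Chromatin silencing genes had 5 rises and 14 falls in 71, with LMNB1, a nuclear lamin, at -0.41 at its promoter and LBR at -0.44. Unfolded protein stress genes had 5 rises and 19 falls in 82, with BAG3 at -0.85 and XBP1 at -0.80. Adjusted over the list alone, these 8 lists had 14 and 23, 34 and 55, 23 and 13, 19 and 21, 23 and 24, 16 and 21, 5 and 14, and 6 and 22 rises and falls, in the order given. With loess offsets they had 15 and 9, 34 and 33, 21 and 10, 23 and 17, 20 and 17, 13 and 22, 7 and 11, and 14 and 15, so the excess of falls near p53 targets turned and that in the AP-1 and unfolded protein lists was nearly gone. For the p53, Hippo, epithelial-mesenchymal and lineage lists the mean was positive while the median and the camera direction were negative, and with loess offsets the camera direction of the p53, Hippo, epithelial-mesenchymal and AP-1 lists turned positive. For the unfolded protein list the median went from -0.06 to 0.03 with loess offsets. The limma camera adjusted p of the senescence, Hippo, epithelial-mesenchymal, lineage, silencing and unfolded protein lists lay between 0.10 and 0.67; the unfolded protein list passed without DMSO replicate 1 (0.047) and without MPS1i replicate 2 (0.049).

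Markers of other cell types were measured as a check. Of 48 peaks near immune cell markers, 5 rose and 3 fell, both in all and adjusted over the list alone (limma camera adjusted p = 0.46). ITGAM stood at 0.70, MS4A1 at 2.23 (SE 0.40) and GNLY at -0.78. The MS4A1 peak lay in an annotated intron of MS4A5, had a mean of only 19.5 counts and stood at 1.39 with loess offsets. The median of the immune list, 0.05, turned to -0.03 with loess offsets. Of 58 near markers of fibroblasts and endothelium, 12 rose and 5 fell, or 13 and 5 adjusted over the list alone (limma camera adjusted p = 0.10, and 0.036 without DMSO replicate 1), with TEK, an endothelial receptor, at 2.23, DCN at 1.30 and CDH5 at 0.74; this list's median was 0.20, and 0.13 with loess offsets.

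**Figure D3:**
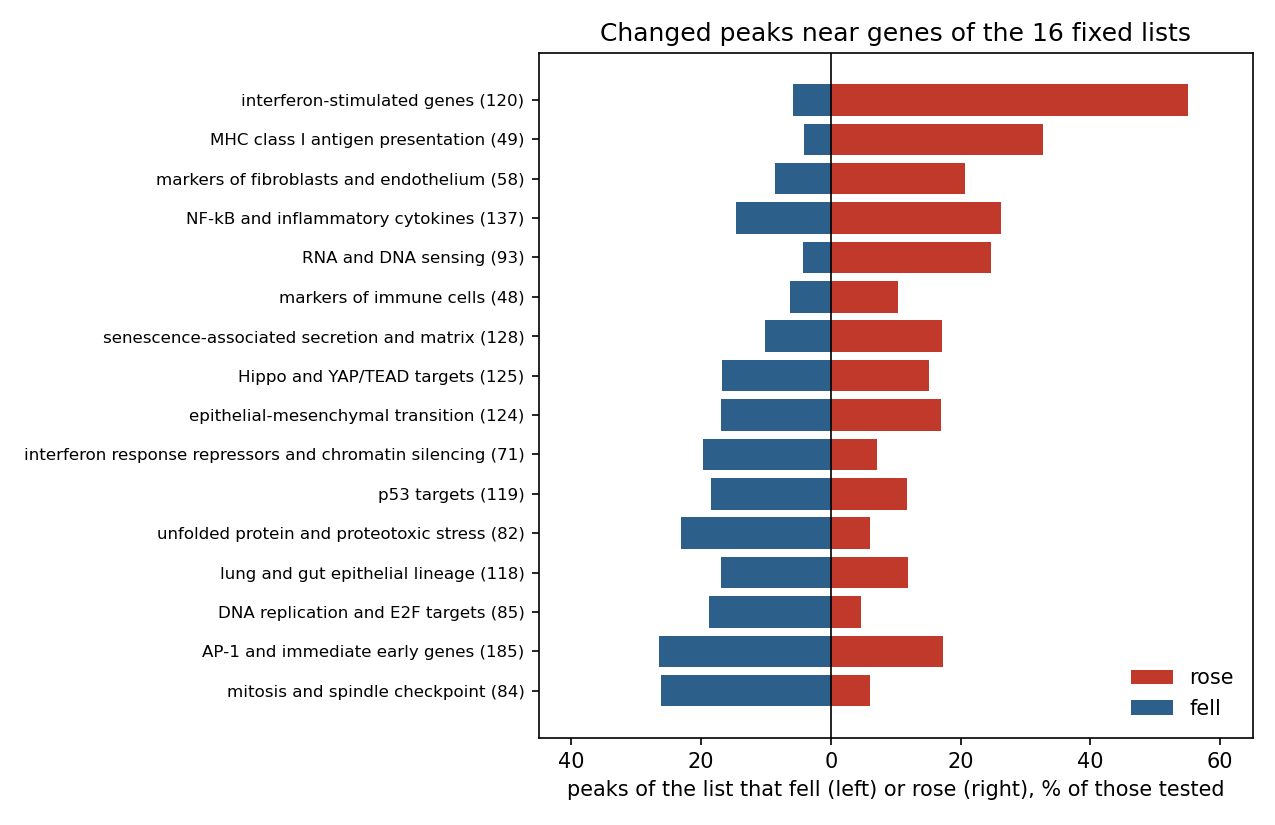
Share of a list's tested peaks that rose (red, to the right) or fell (blue, to the left), in percent. A list's peaks are those whose nearest TSS, within 50000 bp, is that of a list gene. The 16 fixed lists are ordered by median log2 fold change, with the number of peaks in brackets. The interferon-stimulated genes stand at the top, with 66 of 120 peaks up and 7 down, and the mitosis list at the bottom, with 5 of 84 up and 22 down.

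At promoters, 17 of 27 interferon-stimulated genes rose and 15 of 30 mitosis genes fell, or 20 and 6 with loess offsets. Both lists passed limma camera and neither did with an estimated correlation (adjusted p = 0.27 and 0.48). The largest rise was at FNDC11, whose neighbours include the interferon-induced helicase gene HELZ2, from 12.3 ± 0.31 to 79.5 ± 8.6 CPM (SD, n = 2), or 2.70 on the log2 scale (SE 0.08, edgeR adjusted p = 1.4e-106). FBXO39 rose by 2.63 (SE 0.23) and its neighbour XAF1, an interferon-induced promoter of apoptosis, by 2.28 (SE 0.23). OAS2 rose by 2.03 (SE 0.09) and the keratin-associated KRTAP4-6 by 1.91 (SE 0.28). The largest falls were at PPP1R14D (-1.18, SE 0.24), SGCD (-1.07, SE 0.24), NHSL1 (-0.94, SE 0.25), ARHGEF10L (-0.89, SE 0.17) and EFR3A (-0.88, SE 0.17); those of SGCD and NHSL1 were lost with DESeq2 or without MPS1i replicate 1, and that of EFR3A with promoters taken as peaks within 1000 bp of a TSS. The promoter of TTK, which encodes MPS1 itself, fell by 0.25 (SE 0.07, edgeR adjusted p = 0.0063), a call lost with DESeq2, library size alone or loess offsets and without DMSO replicate 2 or MPS1i replicate 1. The promoters of CDKN1A (-0.01, SE 0.06), MDM2 (-0.02, SE 0.06), MAVS (-0.01, SE 0.08) and CXCL8 (0.26, SE 0.15) did not pass. The RIGI promoter rose by 0.32 (SE 0.08), a call lost without DMSO replicate 1.

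Of 10944 promoters, 1010 rose and 1650 fell, so 38% of calls were rises. This split turned with the scaling: rises were 65.8% of calls (1558 against 809 falls) with library size alone and 78.3% (1978 against 547) with loess offsets, which moved the median promoter from -0.04 to 0.06. DESeq2 gave 457 rises and 376 falls, or 54.9% rises. It took its size factors from the promoter counts alone and had a median of 0.0007, so it changed the scaling as well as the test. Rises numbered 536 without DMSO replicate 1, 658 without MPS1i replicate 1 and 637 without MPS1i replicate 2, and falls 832, 887 and 898 without DMSO replicate 1, DMSO replicate 2 and MPS1i replicate 1.

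Of the 16 lists, 6 passed at promoters, and all 6 calls were lost with an estimated correlation, at limma adjusted p between 0.27 and 0.48. With fry, the interferon (limma adjusted p = 0.027) and NF-kB lists (0.042) passed and the sensing (0.063), mitosis (0.079), replication (0.071) and MHC class I lists (0.089) did not. For interferon-stimulated genes 17 of 27 promoters rose and 1 fell, with 18 and 1 adjusted over the list alone (limma camera adjusted p = 2.71e-10; 0.27 with an estimated correlation). For NF-kB and cytokines 8 of 18 rose and 0 fell, with 10 and 0 adjusted over the list alone (limma camera adjusted p = 7.3e-07; 0.41 with an estimated correlation), among them CCL5 (1.53), IL32 (1.07) and the chemokine CXCL1 (0.81). For RNA and DNA sensing 7 of 17 rose and 0 fell, with 7 and 1 adjusted over the list alone (limma camera adjusted p = 0.017; 0.48 with an estimated correlation). Its median was -0.01 and its mean 0.32, since a few members rose strongly, such as AIM2 (1.75), the interferon gene IFNL1 (1.61) and TRAF3 (0.86). For MHC class I 5 of 14 rose and 0 fell, with 6 and 0 adjusted over the list alone (limma camera adjusted p = 0.0036; 0.48 with an estimated correlation), among them TAPBP (0.76), and PDCD1LG2, which encodes the checkpoint ligand PD-L2, rose 2.83-fold. The SEs of the log2 fold changes of promoters named for the lists were 0.07 to 0.23.

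Of 30 mitosis promoters, 0 rose, 15 fell and 15 were not called, with 0 rises and 16 falls adjusted over the list alone. The limma camera adjusted p was 7.7e-04, and 0.48 with an estimated correlation. Among the falls were PLK1 (-0.52), PRC1 (-0.35) and KIF20A (-0.34). Of 26 DNA replication promoters, 0 rose, 11 fell and 15 were not called, with 0 rises and 13 falls adjusted over the list alone. Here the limma camera adjusted p was 0.0051, and 0.48 with an estimated correlation. Falls included the ribonucleotide reductase subunit RRM2 (-0.44), EXO1 (-0.34) and CHEK1 (-0.31). With loess offsets, 6 mitosis promoters fell and 1 rose, and 4 replication promoters fell and 1 rose. The medians shrank from -0.18 to -0.06 for mitosis and from -0.17 to -0.04 for replication, and both lists passed at the preset correlation (limma camera adjusted p = 0.0013 and 0.023). For p53 targets 2 of 26 rose and 8 fell, adjusted over the list alone too, a split that turned to 5 rises and 1 fall with loess offsets (limma camera adjusted p = 0.27); BBC3 rose by 0.78. Of AP-1 promoters 7 of 26 rose and 6 fell, with 8 and 6 adjusted over the list alone (limma camera adjusted p = 0.13, and 0.041, higher, with loess offsets). Of senescence promoters 5 of 13 rose and 0 fell, adjusted over the list alone too (limma camera adjusted p = 0.098, and 0.038 without MPS1i replicate 2). The other 7 lists, immune and fibroblast markers included, did not pass at promoters (limma camera adjusted p between 0.27 and 0.90).

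Rises were rarer at promoter than at distal peaks with TMM and more common with loess offsets. With TMM, 9.36% of the 11864 promoter peaks and 13.1% of the 81702 distal peaks rose (odds ratio 0.683, two-sided Fisher's exact test p = 4.95e-33), and 15.1% and 12.4% fell (odds ratio 1.26, p = 3.02e-16). With loess offsets, 17.4% and 10.5% rose (odds ratio 1.79) and 5.13% and 11% fell (odds ratio 0.437). The odds ratio for falls was also below 1 with library size alone (0.848) and at 0.999, 0.916 and 0.998 without DMSO replicate 1, DMSO replicate 2 and MPS1i replicate 1, and was 1.71 without MPS1i replicate 2. Peaks are not independent replicates.

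Since MPS1 inhibition makes chromosomes missegregate, the share of counts on each chromosome was compared. It differed for 16 of 23 chromosomes, by at most a few percent. These are changes relative to the other chromosomes. The TMM factors of the peaks, in place of the library size, shift all 23 chromosomes alike by -0.067 on the log2 scale, which makes every value negative and leaves the differences between chromosomes as they were. Chromosome 20 rose by 4.47%, from a share of 2.72 ± 0.00081% to 2.84 ± 0.0013% (SD, n = 2), chromosome X by 3.62%, chromosome 15 by 3.61% and chromosome 6 by 2.92%. Chromosome 1 fell most, with a change of -3.79%, from 10.6 ± 0.023% to 10.2 ± 0.04% (SD, n = 2). The edgeR adjusted p was 6.32e-05 for chromosome 20 and 0.0014 for chromosome 1. Chromosomes 9 (1.66%), 13 (2.15%), 16 (1.25%), 21 (2.17%) and 22 (2.12%) also rose, and chromosomes 2 (-1.38%), 3 (-1.04%), 7 (-1.39%), 8 (-1.37%), 10 (-0.78%) and 14 (-0.985%) fell. Chromosome X went from 0.05 on the log2 scale to 0.03 with loess-corrected sums and 0.08 with distal peaks only, chromosome 3 from -0.015 to -0.025 and chromosome 16 from 0.018 to 0.032 with loess-corrected sums, and chromosome 14 from -0.014 to -0.024 with distal peaks only. Chromosome 13 did not pass with loess-corrected sums, and chromosomes 3 and 22 did not pass with distal peaks only. Other chromosomes passed only under these alternatives: 4, 5, 12, 17 and 19 with loess-corrected sums, and 4, 11, 12, 17 and 18 with distal peaks only. Chromosome 19 went from 0.014 to 0.041 and chromosome 4 from 0.00002 to -0.022 with loess-corrected sums. Only 6 chromosomes passed without DMSO replicate 1 and 6 without DMSO replicate 2. A share in peaks reflects both DNA copy number and accessibility.

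**Figure D4:**
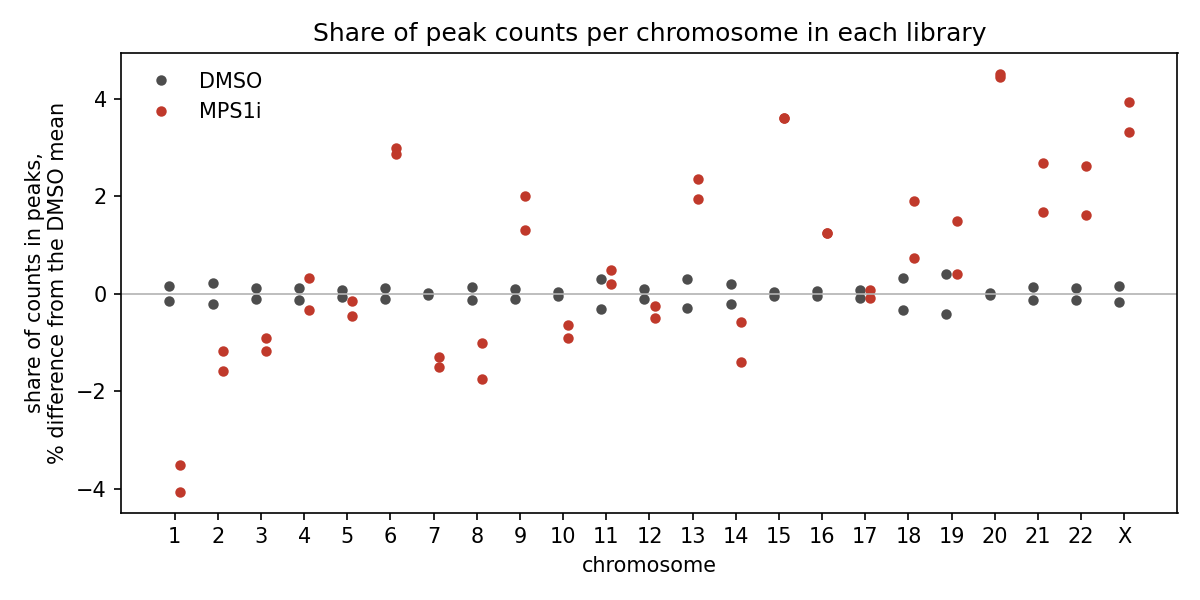
Share of peak counts on each chromosome in each of the 4 libraries, as the percent difference from the mean of the DMSO libraries (grey DMSO, red MPS1i). In the MPS1i libraries chromosome 20 lies 4.47% higher and chromosome 1 at -3.79%, both relative to the other chromosomes; the TMM factors of the peaks shift all chromosomes alike, to negative values.

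By 10 Mb windows, 211 of 310 differed (edgeR), 127 up and 84 down, with a median absolute log2 fold change of 0.036; with TMM over windows 99 were up and 113 down. The strongest falls were on chromosome 1 from 10000001 to 20000000 (-0.13, SE 0.01) and from 50000001 to 60000000 (-0.13, SE 0.01). The strongest rise, 0.70 (SE 0.30) on chromosome 15 from 10000001 to 20000000, rested on 2 peaks and was lost with loess offsets (0.29, edgeR adjusted p = 0.51), and the next, 0.37 (SE 0.03) on chromosome X from 90000001 to 100000000, rested on 44 peaks and stood at 0.21 with loess offsets. These windows were chosen after their values were seen.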

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

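Counts divided by 2, loess-corrected chromosome sums and the tests of repeats were chosen after the data were seen. RLE size factors, no filter on low counts and counts divided by 2 kept every count of changed peaks, and the first 2 every count of changed promoters, within 1.5 times. No named peak or promoter that passed changed sign under any alternative run; the promoters of CDKN1A, MDM2, MAVS and CORO1A, which did not pass, turned from negative to positive with loess offsets and library size alone. Among the 61 named promoters, some of which had not passed in the main test, 10 that had passed were no longer called with DESeq2. The causes of the shifts below were not tested, except that the loess offsets remove the trend with abundance and that leaving out a library, or testing narrower windows, changes what is tested. For rising peaks, DESeq2 gave 3816, a fold above 1.2 gave 6392, and leaving out 1 library gave 7409 to 9141; for falling peaks DESeq2 gave 5088 and a fold above 1.2 gave 3485. For rising promoters, DESeq2 gave 457, library size alone 1558, loess offsets 1978 and leaving out 1 library 536 to 714; for falling promoters these were 376, 809, 547 and 832 to 1640. The odds ratio for rises at promoters turned to 1.79 with loess offsets. That for falls turned to 0.8477 with library size alone and 0.4375 with loess offsets, and ranged from 0.9157 to 1.71 without 1 library. With an estimated correlation 0 lists passed among peaks and 0 among promoters; among peaks 4 passed with loess offsets, 5 within 10000 bp and 2 to 5 without 1 library. Chromosomes that differed ranged from 6 to 17 without 1 library, and 393 of 599 windows of 5 Mb differed. When a library was left out, the lone library of its group was assumed to vary like the other group.

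Over single peaks the replicate numbers showed no pairing, since deviations from the group means correlated at 0.0038 between libraries of 1 number. If both mates were counted, sampling noise at single peaks could hide a pairing. From replicate 1 to 2, the shares of chromosomes 1, 12, 16, 17, 19 and 20 rose in both groups. Those of chromosomes 2, 3, 4, 8, 9, 10, 18 and 21 fell in both. The shares of chromosomes 5, 6, 7, 11, 13, 14, 15, 22 and X moved opposite ways, so more moved alike than not. Whether the numbers pair the libraries stays open. With the replicate block, 11480 peaks rose and 11971 fell, 1036 promoters rose and 1717 fell, 2 and 6 lists passed, and 16 chromosomes and 195 windows differed. The ERV1 repeat family, which did not pass without the block, passed with it (limma camera adjusted p = 0.0488). Motif tests and GC offsets, alone or with the block, were not run for want of the genome sequence. Of simulated peaks changed 1.2-fold, 4% were recovered where 200 peaks changed. In the data, where far more peaks passed, the same adjusted threshold is less strict, so that share does not carry over.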

Other observations

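All tests of repeats and the comparison of chromosomes across peak classes were chosen after the data were seen, as was the test of reads shared between repeat copies; the other tests had their predictions written before their results were seen, but those on ERV1 were run after the median of that family had been seen.

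In certain endogenous retroviral elements more peaks rose than fell. Of 92 LTR elements with at least 20 tested peaks, 3 passed limma camera at the preset correlation with both TMM and loess offsets, all of the ERV1 family, and they also passed without any 1 library. With an estimated correlation 0 of the 92 passed, and these 3 had limma camera adjusted p = 0.48 with TMM and 0.85 with loess offsets. The estimates with loess offsets were -0.016 for LTR8, 0.0053 for LTR8B and -0.0049 for MER51A, all below the preset 0.01. That setting takes its degrees of freedom from the 4 libraries alone, so a failure there says little about these elements. The preset setting takes them from the number of tested peaks, so a pass there does not show that a rise would recur in new libraries. The correlation estimates rest on the same 4 libraries. For LTR8, 34 of 63 peaks rose and 2 fell, with a median log2 fold change of 0.64 (0.45 with loess offsets, limma adjusted p = 5.4e-05). For LTR8B, 29 of 66 rose and 8 fell (loess median 0.27, limma adjusted p = 0.0016), and for MER51A 28 of 69 rose and 0 fell (loess median 0.21, limma adjusted p = 0.0026). None of the peaks in these 3 elements had a gene of the interferon or sensing lists as its nearest gene, and each element's peaks lay on 20 chromosomes. With TMM the strongest was an intergenic LTR8B peak at -29429 bp from the TSS of OXA1L (chromosome 14, 22737071 to 22737448), which rose by 2.41 (SE 0.40, edgeR adjusted p = 3.3e-07); with loess offsets it stood at 1.60, below the LTR8 peak nearest to LINC01173 at 2.07. By whole families 0 of 18 passed with TMM in limma camera, ERV1 coming nearest with 415 of 1997 peaks up and 140 down (adjusted p = 0.058, 0.095 with an estimated correlation, 0.44 with loess offsets and 0.049 without DMSO replicate 1). With loess offsets the 2 families that passed, Alu (adjusted p = 0.047) and RTE-X (adjusted p = 0.019), were lower in limma camera. Fry, which does not compare a family with other peaks, passed with TMM for 7 families, all upward: ERV1 and ERVL-MaLR (limma adjusted p = 0.018 each) and ERVL, hAT-Blackjack, L1, L2 and TcMar-Tigger (0.040 each). The median log2 fold changes of these 7 families were 0.06 to 0.16 with TMM, but only -0.005 to 0.05 with loess offsets. Their upward direction thus depends largely on the scaling.

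Weak peaks rose and strong peaks fell. A difference between single libraries was argued against: all 4 slopes of the log2 ratio on abundance between groups were negative, and the shallowest was 5.99 times as steep as the steeper slope within a group. More background reads per base pair in the MPS1i libraries is a candidate explanation that stays open, since it predicts that longer peaks of like count rise more, and the median Spearman's rho across peaks over 10 count deciles was 0.167. This correlation was however largest, at 0.301, among the strongest peaks, where added background would weigh least. A true change of weak sites also stays open and was not tested.

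Peaks near interferon-stimulated genes rose. The abundance trend was argued against as the whole cause, as the list's median above that of all peaks with loess offsets was 0.986 times that with TMM. Immune cells mixed into the MPS1i libraries were argued against as well. With loess offsets the median of immune marker peaks was -0.0344 (95% bootstrap interval -0.14 to 0.09), against 0.45 for the interferon list. Such cells were unlikely from the outset in an established cell line, so this outcome adds little. A response of the NCI-H1944 cells to the pulse remains as a hypothesis, found and tested on the same data, and the offsets for GC content that could bear on it were not run.

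The median ERV1 peak lay above that of all peaks with TMM (0.15), though the family did not pass camera there. The loess median of 0.0521 (95% bootstrap interval 0.03 to 0.07) lay above the central 95% of 1000 random sets matched on count and length (-0.01 to 0.03). Both ranges treat peaks as independent and leave out the spread between libraries, and they overlap, from 0.0319 against up to 0.0343. With loess offsets the family did not pass limma camera (adjusted p = 0.44). The abundance trend as the whole source therefore stays open. Leaving out the 6 of 1997 peaks nearest to genes of the interferon and sensing lists gave a ratio of 1 to the median of all ERV1 peaks, which decides nothing about peaks near interferon-stimulated genes, since no 6 peaks taken out of the set could have brought it below 0.975. Reads shared between near-identical copies would also raise younger families. The loess medians of ERVK and Alu were -0.0800 and -0.10, both below the bootstrap interval of ERV1. No biological explanation was tested.

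Chromosome shifts were compared between promoter and distal peaks. With loess-corrected sums chromosome 1 stood at -0.05 and chromosome 20 at 0.06 on the log2 scale, against -0.06 and 0.06 without the correction. Across 23 chromosomes, the median loess log2 fold change of promoter peaks and that of distal peaks correlated with Pearson's r of 0.57 (permutation p = 0.0046, adjusted over 2 relations 0.0093) and Spearman's rho of 0.60 (permutation p = 0.0033, adjusted 0.0067). Without chromosomes 20 and 1, whose promoter values lay farthest from the median, r was 0.36, so the relation rests in part on them. By distal values chromosome X stood highest, at 0.068, with a promoter value of 0.046. The share of promoter peaks on a chromosome and its distal median gave r of 0.11 (permutation p = 0.62, adjusted 0.62) and rho of 0.24 (permutation p = 0.27, adjusted 0.27). The permutations treat chromosomes as replicates and leave out the spread between libraries. Both peak classes come from the same 4 libraries, and chromosome sums differed within groups by more than sampling noise. These p-values thus do not tie a relation to the treatment.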
